A study of Mus musculus with 26 samples.

How the data were processed

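RNA from 100 sorted cells per library was amplified with a SMART-Seq kit for low input and sequenced, per the labels' protocols. This kit does not mark the strand of a transcript. The submitters' processing notes name bcl2fastq 2.17, Bowtie2, STAR 2.5.3a, Partek, DESeq2 and the build mm10, without saying which step each served. Which aligner gave the deposited values, the annotation release and the treatment of multi-mapping reads are not given in the sources used here.

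The authors deposited a table of estimated counts per gene (expected counts), with fractions where a read was shared between features, for 25100 genes in 26 libraries. Every gene in it has a total of at least 10. A second deposited table holds normalized values, a signal in arbitrary units, for 24806 genes. Of its values, 99.96% equal the rounded count times 1 constant per library, within 0.05 reads. The same deposited table gives adjusted p-values of the authors' own comparisons, of which the design and unit of replication are not stated. No value column was left unmapped. Gene positions in the count table were compared with GENCODE M21 of the same build. Of 24459 genes matched by name and chromosome, 97.0% had the same start and 96.7% an end 1 base below the listed stop, so ends are given here as the stop minus 1. The count table lists 0 genes on the mitochondrial chromosome, and 11 nuclear pseudogenes that resemble mitochondrial genes hold 6.16% to 8.53% of a library's counts. Their share was 7.58 ± 0.51% in PBS, 7.19 ± 0.52% in Ova and 6.34 ± 0.17% in pIC libraries (SD over libraries). Reads in such copies cannot be assigned with certainty.

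Libraries were grouped by treatment from the labels. The middle of each title carries a number shared by 1 to 3 libraries of 1 treatment, whose meaning the labels do not state. Libraries with a shared number may come from 1 animal, so their counts, rounded to whole numbers, were summed into 11 pools (PBS 3, Ova 5, pIC 3), and the pool was the replicate. The labels do not say that pools are separate animals, so p-values measure the spread between these pools, which may be technical. Mmrn1 was absent from all libraries of 4 pools and present in all libraries of the other 7, which fell on 1 of 3 PBS, 1 of 5 Ova and 2 of 3 pIC pools. A fit with its presence as a covariate, chosen after this was seen, gave 11, 0 and 15 called genes in pIC against PBS, Ova against PBS and Ova against pIC. Libraries with a shared number deviated from their group mean more alike than others did. The mean correlation of deviations was -0.0618 over 20 such pairs and -0.127 over 92 other pairs (one-sided permutation test within treatments, 100000 resamples, p = 7e-05). The correlation that limma estimated for such libraries was 0.0959. The highest correlation between 2 libraries was 0.910, and none was taken for a duplicate.

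Pools were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr, 1 fit over the 3 groups, robust quasi-likelihood F-tests and Benjamini-Hochberg adjustment at 0.05. This left 17464 genes. The common biological coefficient of variation was 0.526 over pools and 0.659 over single libraries. Genes on X and Y were scaled by TMM over all genes in the table, since not all Y genes passed the filter. Standard errors were derived from the F statistic. Adjusted p-values are those of edgeR unless limma 3.58.1 or DESeq2 1.42.0 is named. A list of genes was tested with limma's camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over 25 lists in each comparison. The lists were fixed before the data were examined; 1 further list, of mitochondrially encoded transcripts, had no measured member. With an estimated correlation, and by fry's directional test, the interferon-stimulated list was called in pIC against PBS and in Ova against pIC, and no other list was called in any comparison. Fry's mixed test, which asks for change in either direction, called further lists, among them megakaryocyte and platelet (adjusted p = 2.08e-06) and HSC identity (adjusted p = 0.00148) in pIC against PBS. The sign of a list's median differed from camera's direction for 2 lists in pIC against PBS, 1 in Ova against PBS and 3 in Ova against pIC.

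The genes named were set by a rule fixed in advance. It took, in each comparison, genes past the threshold with a mean of at least 10 CPM and no overlap between the pools of the groups, up to 10 with the largest rise and 6 with the largest fall. Where fewer than 10 genes passed, all that passed and the 5 of smallest p that did not were taken. The 3 members of smallest p in each of the 5 lists of smallest camera p and the sort genes Fgd5, Slamf1, Kit and Ly6a were added. Xist and genes on Y were outside the rule. Other genes named, among them Xist, Pdcd4, C1galt1, Pf4 in pIC against PBS and further list members, were chosen after their values were seen.

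The procedure was tested on simulated counts drawn with the real abundances, depths and dispersions, with 200 genes changed 2-, 4- or 8-fold in each of 3 draws per comparison. In the pool-level simulations of pIC against PBS, 12 of 235 calls were false, and in those of Ova against PBS 13 of 301. Alternatives covered the unit of replication, scaling, filters, the test, the samples in the fit and leaving out each pool or library. After the counts of called genes were seen, 4 alternatives were added, and the limma-voom values and the lists followed across settings were chosen for display. Figures were drawn with matplotlib 3.10.9.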

Results

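Gene expression was measured in haematopoietic stem cells, the bone marrow cells from which all blood lineages arise, of mice that carried an mCherry reporter at Fgd5, a gene whose expression in marrow marks these cells. Each library was made from 100 sorted cells that lacked lineage markers, carried Sca-1, c-Kit and CD150, and expressed the reporter. The 26 libraries fell into 3 groups. The Ova group of 12 libraries came from mice with an allergic peritonitis, which had been sensitised with ovalbumin in aluminium hydroxide, challenged with 10 µg ovalbumin on day 14 and killed 48 h later. The pIC group of 5 libraries came from mice given 200 µg poly I:C, a double-stranded RNA mimic that induces type I interferon, 24 h before harvest. The PBS group of 9 libraries served as the control.

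Library totals lay between 6114993 and 12684852 counts in the PBS group, between 3205978 and 9484661 in the Ova group and between 1825780 and 8310511 in the pIC group. Libraries whose titles shared a number were summed into 1 pool, which gave 3 PBS, 5 Ova and 3 pIC pools. Pool totals were 24155961 to 34431879 for PBS, 12460254 to 17044311 for Ova and 1825780 to 14273225 for pIC. The smallest, the pIC pool with the number 14, was a single library. Values below are mean CPM, scaled by TMM, ± SD over pools unless stated otherwise, and fold changes are log2 ± SE.

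The genes used for the sort were read in every group and are given as context. Fgd5 was at 42.2 ± 13.0 CPM in PBS pools, 41.0 ± 6.04 CPM in Ova pools and 34.4 ± 2.69 CPM in pIC pools. Slamf1, which encodes CD150, was at means of 42.5, 41.5 and 29.9 CPM in the same order. Kit was at 497 ± 51.5, 465 ± 27.6 and 376 ± 39.0 CPM. Ly6a, which encodes Sca-1, was at 453 ± 47.0, 607 ± 158 and 1058 ± 187 CPM. The X-inactivation transcript Xist was at 1335 to 2848 CPM in 10 of the 11 pools, and at 2.69 CPM in the pIC pool with the number 12, scaled by TMM over all genes in the table. Both libraries of that pool were low, at 5.90 and 1.18 CPM. Mmrn1, a platelet and endothelial multimerin gene, was at 0 to 0.270 CPM in every library of 4 pools (PBS 5, Ova 8, pIC 12 and pIC 13) and at 83.1 to 327 CPM in every library of the other 7.

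**Figure D1:**
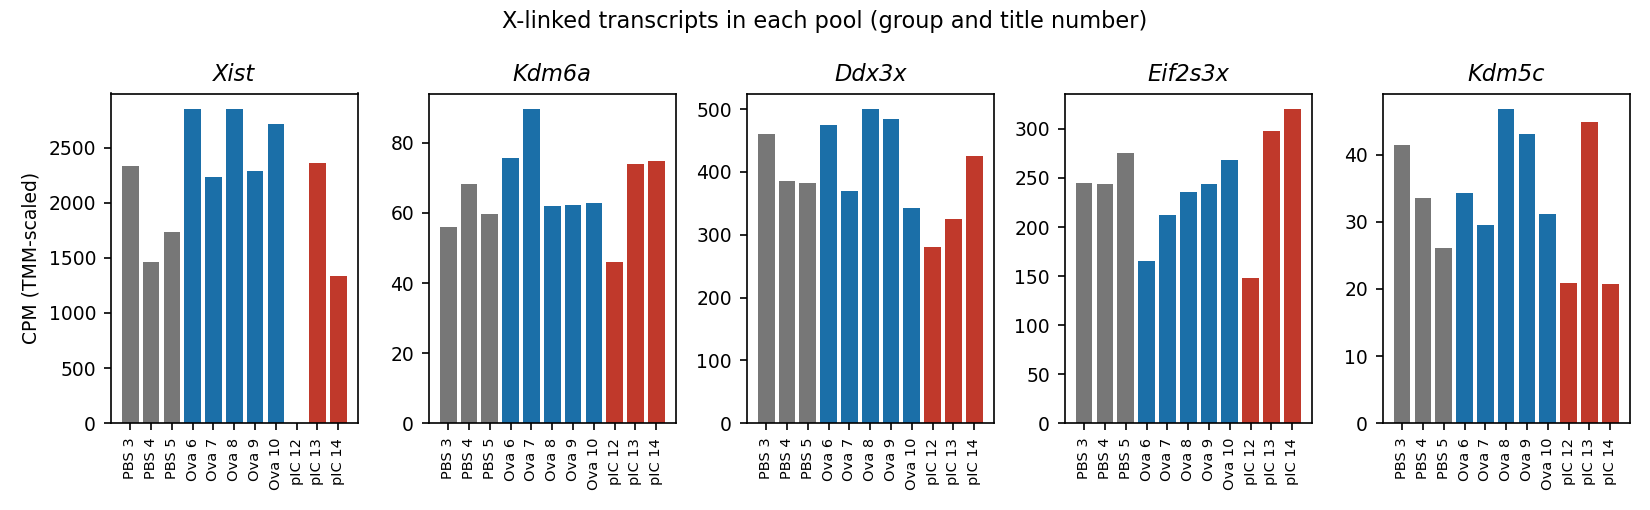
Bars give CPM, scaled by TMM over all genes in the table, of Xist and of 4 X-linked genes that escape X inactivation in each of the 11 pools, named by group and title number (grey PBS, blue Ova, red pIC). Xist is at 2.69 CPM in pIC pool 12 and at 1335 CPM or more in every other pool, and Kdm6a, Ddx3x and Eif2s3x are each lowest in pool 12.

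The first comparison, pIC against PBS, showed how the sorted cells differed after a known interferon inducer. Whether stem cells changed or other cells entered the sort is taken up below. Interferon-stimulated genes rose together 24 h after poly I:C. Of the 50 listed and measured, 33 rose and 0 fell when p-values were adjusted over the list alone, and 2 rose over all genes tested. The median log2 fold change of the list was 1.06 (camera, adjusted p = 4.36e-40; adjusted p = 0.0301 with an estimated correlation). Genes that passed over all genes tested were few: 5 of 17464, of which 2 rose and 3 fell.

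Ifit1, whose product binds viral RNA that lacks the cap methylation of host transcripts, rose from 34.2 ± 7.68 to 135 ± 58.6 CPM (n = 3 pools each). Its log2 fold change was 1.97 ± 0.30 (edgeR quasi-likelihood test, adjusted p = 0.0454), and it was above the highest PBS library in 5 of 5 pIC libraries. Ifitm3, a membrane protein that restricts virus entry, rose from 1052 ± 79.9 to 2164 ± 295 CPM, by 1.04 ± 0.15 (adjusted p = 0.0454), also in 5 of 5 libraries. Within the interferon-stimulated list, the oligoadenylate synthetase Oas2 rose by 2.28 ± 0.51 and Oas1a by 1.46 ± 0.30, adjusted over the list alone. Ifit3 (4.13 ± 1.01), Irf7 (1.97 ± 0.53), Rtp4 (1.40 ± 0.29), Slfn5 (1.28 ± 0.23) and Cmpk2 (1.89 ± 0.37) passed in the same way. Mx1 (1.86 ± 0.89) did not. Oas1g (1.83 ± 0.30) and Rnf213 (1.08 ± 0.18), which lay outside the list, were among the 5 genes of smallest p that did not pass over all genes tested (adjusted p = 0.0627 for each).

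The 3 genes that fell were Slc18a2, Chad and Gpx3. Slc18a2, a vesicular monoamine transporter, went from 478 ± 15.3 to 214 ± 26.4 CPM and fell by 1.16 on the log2 scale (SE 0.14, adjusted p = 0.0205). Chad, a leucine-rich cartilage matrix protein gene, went from 28.1 ± 6.05 to 2.76 ± 1.49 CPM and fell by 3.50 (SE 0.51, adjusted p = 0.0454). Chad lies within Acsf2 on the other strand, and the library kit does not mark strand. Gpx3, an extracellular glutathione peroxidase gene, went from 18.4 ± 2.45 to 0.525 ± 0.647 CPM and fell by 4.74 (SE 0.72, adjusted p = 0.0454). Each of the 3 lay below the lowest PBS library in 5 of 5 pIC libraries. Ier3, Txnip (which overlaps Gm15441) and Pisd-ps1 had log2 fold changes of -1.17 ± 0.19, -1.34 ± 0.23 and -2.03 ± 0.35 and did not pass (adjusted p = 0.0625, 0.0627 and 0.0627). In mm10, Ifit1 spans positions 34640871 to 34650009 of chromosome 19 and Slc18a2 positions 59260878 to 59296012 of the same chromosome. Ifitm3 lies at 141009586 to 141010770 on chromosome 7, and Gpx3 and Chad start at 54902453 and 94565047 on chromosome 11.

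**Figure D2:**
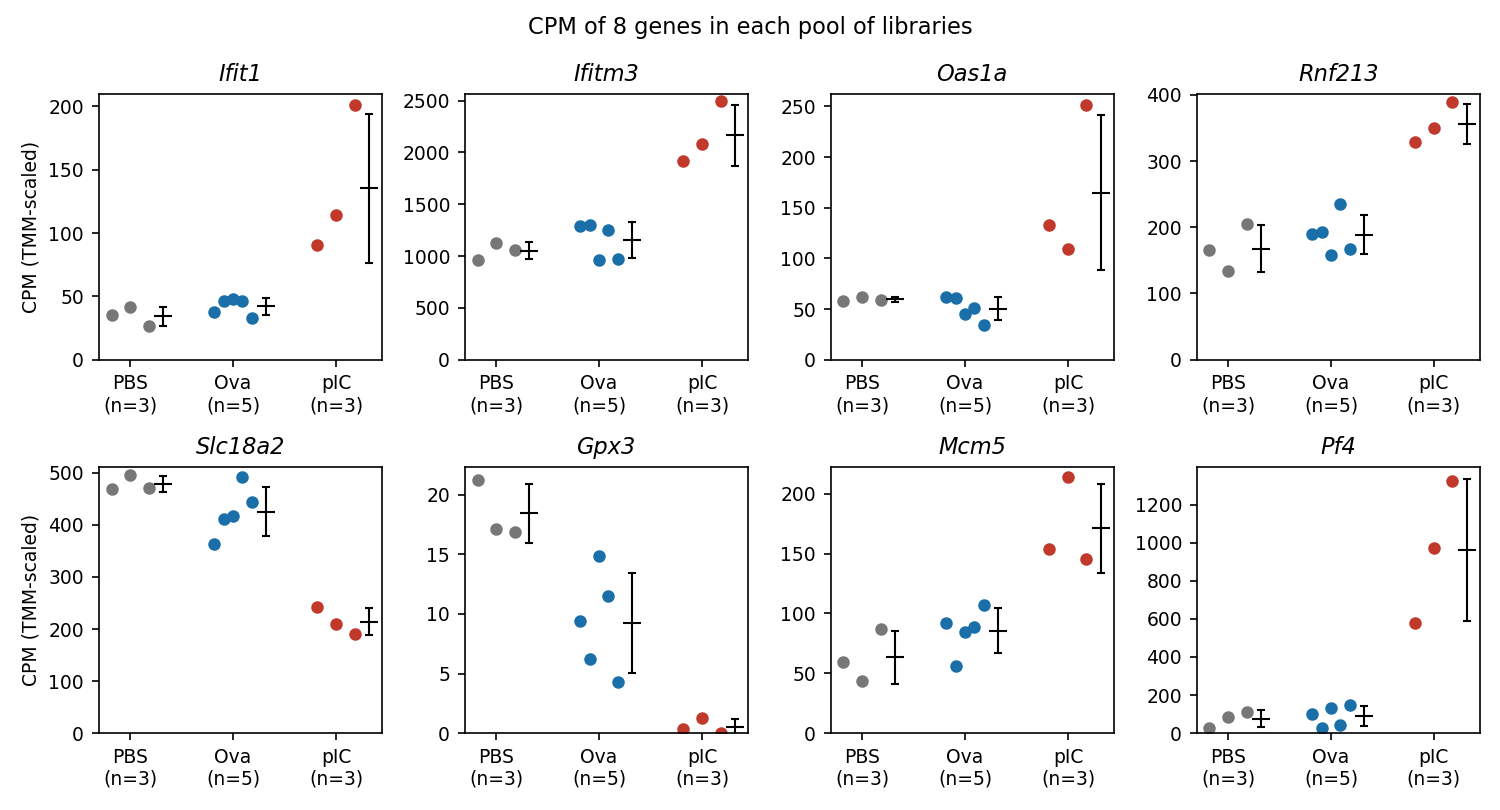
Points give TMM-scaled CPM of 8 genes in each pool, with the group mean and SD beside them (3 PBS, 5 Ova and 3 pIC pools). Ifit1 is at 135 ± 58.6 CPM in pIC pools against 34.2 ± 7.68 in PBS and 42.1 ± 6.67 in Ova pools, and Slc18a2 is at 214 ± 26.4 CPM in pIC pools against 478 ± 15.3 and 426 ± 47.3.

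Genes of DNA replication lay higher in pIC pools as a group. The S phase list of 31 genes had a median log2 fold change of 0.89 (camera, adjusted p = 3.50e-14), but adjusted p = 0.551 with an estimated correlation. The helicase subunit genes Mcm5 (1.44 ± 0.28) and Mcm3 (1.08 ± 0.27) and Uhrf1 (1.84 ± 0.50), which encodes a factor that maintains DNA methylation, rose when adjusted over the list alone. The other 28 members did not pass, and no member passed over all genes tested. With libraries kept apart, limma-voom called 8 members higher over all genes and 20 adjusted over the list alone, and edgeR called 4 and 9. The 31 genes of the G2 and M phase list had a median of 0.09 (camera, adjusted p = 0.392; adjusted p = 0.912 with an estimated correlation).

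Genes of translation and respiration shifted by smaller amounts. Nuclear-encoded respiratory chain genes had a median of 0.26 (79 genes; camera, adjusted p = 1.20e-08; adjusted p = 0.590 with an estimated correlation). Adjusted over the list alone, 12 of them rose, among them Atp5k (0.74 ± 0.17), Cox6a1 (0.58 ± 0.14) and Ndufs6 (0.74 ± 0.18), and 1 fell. Cytosolic ribosomal protein genes had a median of -0.16 (87 genes; camera, adjusted p = 0.00114; adjusted p = 0.685 with an estimated correlation). Of these, 9 fell and 1 rose adjusted over the list alone, with Rps3a1 at -0.44 ± 0.10, Rpl3 at -0.46 ± 0.11 and Rps7 at -0.48 ± 0.12. The immediate early list had a median of -0.31 (21 genes; camera, adjusted p = 0.00520; adjusted p = 0.647 with an estimated correlation). Egr1 (-1.35 ± 0.32), Ier2 (-1.20 ± 0.21) and Dusp2 fell within it, adjusted over the list alone.

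Interferon-gamma-inducible GTPases and chemokines had a median of 0.34 (22 genes; camera, adjusted p = 0.00492; adjusted p = 0.590 with an estimated correlation), and 0 passed adjusted over the list alone. Iigp1 was at 0.91 ± 0.33, Gbp7 at 0.60 ± 0.23 and Cxcl10 at 4.68 ± 1.78, none of which passed. Cxcl10 was at 17.0, 36.6 and 423 CPM in pIC pools 12, 13 and 14, of which the last is a single library. The MHC class I list (median 0.18, camera adjusted p = 0.0267) and the heat shock list (median 0.48, camera adjusted p = 0.00560) were called by camera, with adjusted p = 0.647 and 0.590 with an estimated correlation. Tap1 and Psme2 rose in the first and Hspe1 in the second, adjusted over the list alone.

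Stem cell and lineage transcripts also differed. The HSC identity list of 32 genes had a median of -0.26 (camera, adjusted p = 0.00520; adjusted p = 0.590 with an estimated correlation). Adjusted over the list alone, Sult1a1 (-1.97 ± 0.37), Pdzk1ip1 (-0.75 ± 0.18), Kit (-0.40 ± 0.13) and Ptprcap fell. The platelet chemokine gene Pf4 was at 960 ± 373 CPM in pIC pools against 75.6 ± 44.2 CPM in PBS pools, with a log2 fold change of 3.66 ± 0.64 (adjusted p = 0.0627 over all genes tested). It passed adjusted over the megakaryocyte and platelet list alone, where 6 of 18 genes rose and 5 fell (camera, adjusted p = 0.239; adjusted p = 0.685 with an estimated correlation). In the neutrophil and monocyte list (camera, adjusted p = 0.239; adjusted p = 0.724 with an estimated correlation), Ms4a3 rose (4.54 ± 0.87) and Csf3r fell. Elane (5.22 ± 1.45) and F13a1 passed adjusted over the list alone but were carried by the pIC pool 13: Elane was at 2.54, 106 and 0 CPM and F13a1 at 0.902, 24.7 and 0 CPM in pIC pools 12, 13 and 14. Car1, Ermap and Tfrc passed adjusted over the list alone among 16 erythroid genes (camera, adjusted p = 0.0147; adjusted p = 0.590 with an estimated correlation). Car1 was above the highest PBS library in 3 of 5 pIC libraries. Macrophage and dendritic cell genes had a median of 0.72 (15 genes; camera, adjusted p = 0.00560; adjusted p = 0.590 with an estimated correlation), and 0 passed.

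**Figure D3:**
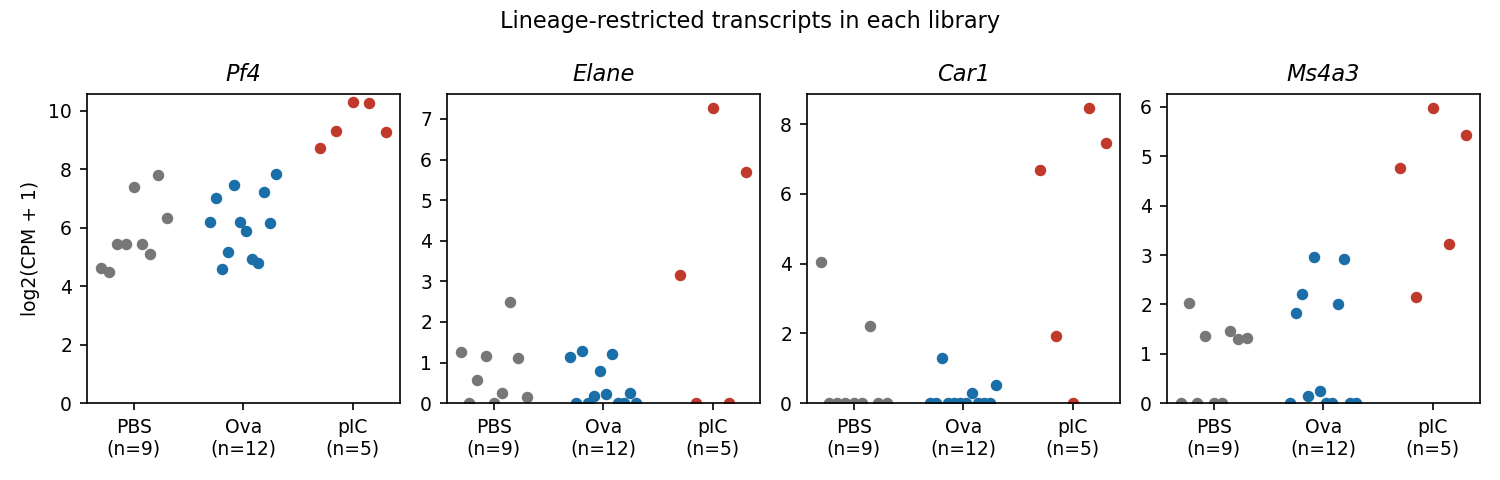
Points give log2(CPM + 1) of Pf4, Elane, Car1 and Ms4a3 in each of the 9 PBS, 12 Ova and 5 pIC libraries. Pf4 and Ms4a3 lie above the highest PBS library in 5 of 5 pIC libraries, and Elane and Car1 in 3 of 5.

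The count of genes passing in this comparison rested on how libraries were treated, on the test and on the filter. With the same pools DESeq2 called 519 genes, and edgeR called 57 among genes with at least 10 CPM in at least 3 pools. With libraries kept apart and a correlation allowed between those that share a title number (limma-voom), 286 genes passed, 176 higher and 110 lower, and 4 of the 5 above were among them. All 286 had the same sign in the pools, which are sums of the same libraries, so this is no independent support for the calls. The count of 5 became 0 without the PBS pools 4 or 5, the Ova pool 7 or the pIC pool 14, 1 without the Ova pool 9 or the pIC pool 13, 2 without the PBS pool 3 and 3 without the Ova pools 6 or 8 or the pIC pool 12. Among single libraries it became 29 without pIC library 2, 10 without PBS library 8, 3 without PBS library 5 or Ova library 11, 2 without PBS library 6 or Ova library 6, and 1 without PBS libraries 2 or 4 or Ova libraries 1, 2, 3, 4 or 9. Interferon-stimulated genes that rose adjusted over the list alone numbered 36, 32 and 22 without the pIC pools 12, 13 and 14.

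The second comparison, Ova against PBS, set sorted marrow cells of mice with allergic peritonitis against those of control mice. No adjuvant dose, injection schedule or harvest time was recorded for PBS libraries, and no group is labelled as given aluminium hydroxide alone or sensitised without challenge. A difference here may come from the adjuvant, the sensitisation, the challenge or the time since injection. These cannot be told apart. No gene passed: 0 of 17464 by the edgeR quasi-likelihood test, with a smallest adjusted p of 0.630. An unadjusted p under 0.05 was found for 1062 genes, or 6.08% of those tested. With libraries kept apart, limma-voom called 12 genes (4 higher, 8 lower), and DESeq2 on the pools called 41. The authors' deposited table has 107 genes at an adjusted p under 0.05.

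The genes nearest to the threshold are given as values only. Thbs1, which encodes the matrix protein thrombospondin-1, was at 20.3 ± 4.31 CPM in Ova pools (n = 5) and 64.1 ± 19.3 CPM in PBS pools (n = 3), a log2 fold change of -1.66 ± 0.30 (edgeR, adjusted p = 0.630). Chad was at 7.06 ± 2.12 against 28.1 ± 6.05 CPM (-1.99 ± 0.38, adjusted p = 0.654). Tmod1, a tropomodulin that caps actin filaments, was at 14.2 ± 3.74 against 2.45 ± 1.48 CPM (2.53 ± 0.49, adjusted p = 0.654). Ern1, the IRE1 sensor of the unfolded protein response, was at 55.4 ± 12.1 against 106 ± 3.21 CPM (-0.94 ± 0.19, adjusted p = 0.658). The transcript 9030619P08Rik was at 42.5 ± 7.29 against 94.7 ± 31.4 CPM (-1.15 ± 0.26, adjusted p = 0.804). Thbs1, Chad, Tmod1 and Ern1 were among the 12 genes that limma-voom called, with adjusted p of 0.0290, 0.0370, 0.0175 and 0.0233.

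The interferon-stimulated list did not pass between Ova and PBS. Its median log2 fold change was 0.19 (camera, adjusted p = 0.0685; adjusted p = 0.900 with an estimated correlation), and 0 of 50 genes passed adjusted over the list alone. Ifit1 differed by 0.30 ± 0.26 and Ifitm3 by 0.13 ± 0.13 (adjusted p = 0.868 and 0.878). The camera test passed under 8 other settings, with adjusted p between 0.00151 and 0.0466, and in 15 of 37 refits without 1 pool or library. Interferon-gamma-inducible GTPases and chemokines had a median of 0.45 (camera, adjusted p = 0.00166; adjusted p = 0.752 with an estimated correlation), and 0 of 22 passed adjusted over the list alone. Iigp1, an immunity-related GTPase gene, was at 248 ± 131 CPM in Ova pools and 125 ± 4.49 CPM in PBS pools (0.98 ± 0.30). Gbp7 was at 0.57 ± 0.21 and the transcription factor gene Irf1 at 0.60 ± 0.22. Without the Ova pool 6 the list's median was 0.18 and its call was lost (camera, adjusted p = 0.0802).

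Genes of mitosis lay lower in Ova pools as a group. The G2 and M phase list of 31 genes had a median of -0.47 (camera, adjusted p = 2.19e-07; adjusted p = 0.752 with an estimated correlation), and 29 of its members had negative fold changes. No member passed adjusted over the list alone. With libraries kept apart, limma-voom gave a median of -0.78 with 5 members lower adjusted over the list alone, and edgeR called 0. Ckap2l was at -1.15 ± 0.39, Cdc20, an activator of the anaphase-promoting complex, at -1.13 ± 0.40 and Kif20a at -1.49 ± 0.66. The median was -1.01 without the Ova pool 10 and -0.23 without the Ova pool 9. The S phase list had a median of -0.14 (camera, adjusted p = 0.403; adjusted p = 0.900 with an estimated correlation).

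Unfolded protein and integrated stress response genes had a median of -0.25 (18 genes; camera, adjusted p = 0.00700; adjusted p = 0.752 with an estimated correlation), with Herpud1 at -0.69 ± 0.19, Xbp1 at -0.53 ± 0.20 and Hspa5 at -0.36 ± 0.16. Erythroid genes had a median of -0.75 (16 genes; camera, adjusted p = 0.00700; adjusted p = 0.752 with an estimated correlation), with Car1 at -3.56 ± 1.39, Car2 at -0.38 ± 0.19 and Epor at -0.85 ± 0.56. Its globin genes differed widely between libraries of the same group. Hbb-bs was at 6.85 to 10674 CPM in PBS libraries and 3.79 to 8587 CPM in Ova libraries, with a log2 fold change of -1.75 ± 1.83, so the list's median carries this spread. The megakaryocyte and platelet list had a median of -0.13 (camera, adjusted p = 0.0441; adjusted p = 0.752 with an estimated correlation). In it Thbs1 fell adjusted over the list alone, while Gp9 (-0.83 ± 0.28) and Gp1ba (adjusted p = 0.810) did not pass.

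The lists chosen for type 2 inflammation did not pass. Type 2 cytokine receptors and STAT6 targets had a median of 0.04 over 18 measured genes (camera, adjusted p = 0.833; adjusted p = 0.900 with an estimated correlation). Il4ra, a subunit of the interleukin-4 and interleukin-13 receptors, differed by 0.35 ± 0.43 and Stat6 by 0.07 ± 0.17. Of 19 listed eosinophil, basophil and mast cell genes, 7 were measured, with a median of 0.17 (camera, adjusted p = 0.869; adjusted p = 0.900 with an estimated correlation). The HSC identity list had a median of 0.02 (camera, adjusted p = 0.763; adjusted p = 0.900 with an estimated correlation).

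At this number of pools, many changes would be missed. In counts simulated for Ova against PBS over 17019 genes, 17.9% of genes changed 2-fold were called, 54.2% of those changed 4-fold and 70.2% of those changed 8-fold. The same shares for pIC against PBS, over 17086 genes, were 12.4%, 42.3% and 56.6%.

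**Figure D4:**
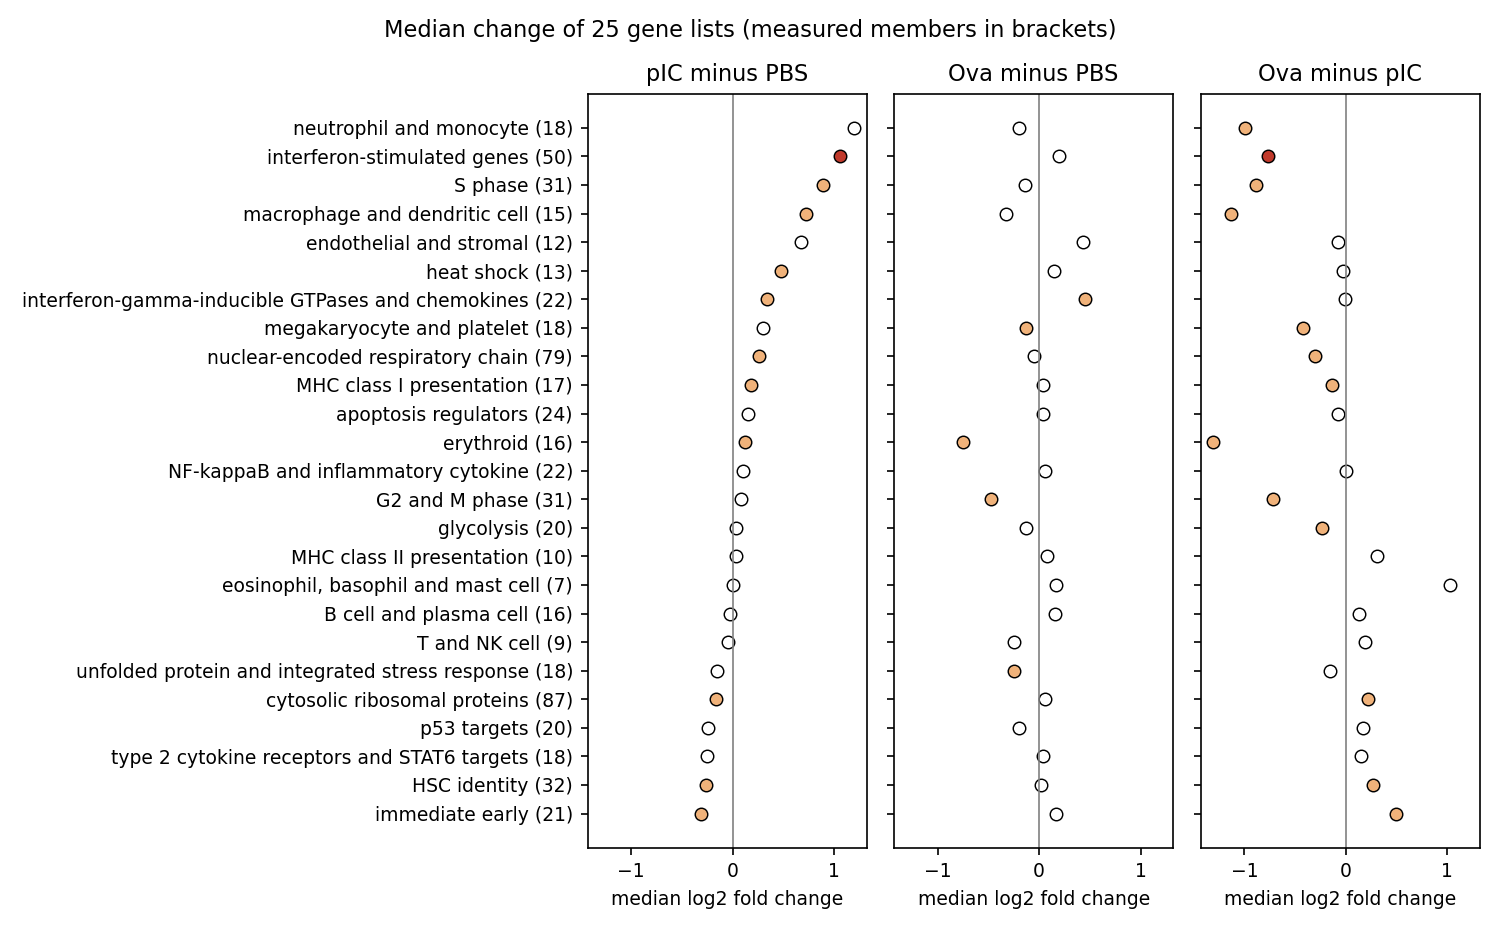
Points give the median log2 fold change of the members of 25 gene lists in each comparison, with measured members in brackets. Filled red points passed camera with a preset and with an estimated correlation, orange points only with the preset one, and open points with neither; interferon-stimulated genes are at 1.06, 0.19 and -0.77 in the 3 comparisons.

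The third comparison set Ova directly against pIC. Harvest was 48 h after the last injection in Ova mice and 24 h after it in pIC mice. A difference here may come from the stimulus or from the time since injection, and the 2 cannot be told apart. Interferon-stimulated genes lay lower after Ova: 32 of 50 fell and 0 rose adjusted over the list alone, and 3 fell over all genes tested. The median was -0.77 (camera, adjusted p = 3.64e-41; adjusted p = 0.0308 with an estimated correlation). Over all genes, 11 passed, of which 2 were higher and 9 lower in Ova. The 3 interferon-stimulated genes were Ifit1 (-1.67 ± 0.25), Oas1a (-1.70 ± 0.26) and Ifitm3 (-0.91 ± 0.13), each with adjusted p = 0.0305 by edgeR. Ifit1 and Ifitm3 were below the lowest pIC library in 12 of 12 Ova libraries.

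The other genes lower in Ova than in pIC included lineage transcripts. Pf4 was at 90.4 ± 52.4 CPM in Ova pools and 960 ± 373 CPM in pIC pools (-3.41 ± 0.52, edgeR adjusted p = 0.0358). Car1, the carbonic anhydrase gene of erythroid cells, was at 0.168 ± 0.271 against 163 ± 184 CPM (adjusted p = 0.0305). It was at 0 CPM in pIC library 3 and 2.83 CPM in pIC library 2, 0 of 12 Ova libraries lay below the lowest pIC library, and with libraries kept apart its adjusted p was 0.459 by limma-voom and 0.00116 by edgeR. Serpine2, a serine protease inhibitor gene, was at 3.02 ± 1.56 against 48.0 ± 20.1 CPM (-3.99 ± 0.62, adjusted p = 0.0358). Slc14a1, a urea transporter gene, was at 43.7 ± 8.28 against 131 ± 33.1 CPM (-1.58 ± 0.22, adjusted p = 0.0305). Pdcd4 (-1.15 ± 0.15) and C1galt1 (-1.16 ± 0.19) were also lower, with adjusted p of 0.0227 and 0.0420. Slc18a2 was higher in Ova, at 426 ± 47.3 against 214 ± 26.4 CPM (0.99 ± 0.13, adjusted p = 0.0227). The second gene higher in Ova, Gm37376 (1.21 ± 0.19, adjusted p = 0.0360), lies inside Malat1 on the other strand, and the 2 cannot be told apart here.

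S phase genes had a median of -0.89 in Ova relative to pIC (camera, adjusted p = 1.16e-23; adjusted p = 0.188 with an estimated correlation). Of the 31, 11 fell adjusted over the list alone, among them Mcm5, Mcm3 (-0.90 ± 0.23) and Gmnn (-1.11 ± 0.29). The G2 and M phase list had a median of -0.72 (camera, adjusted p = 2.62e-09; adjusted p = 0.350 with an estimated correlation). There Ckap2l fell (-2.25 ± 0.40), while Mki67 (-1.07 ± 0.42) and Top2a (-0.95 ± 0.38) did not pass. Respiratory chain genes had a median of -0.30 (camera, adjusted p = 1.39e-16; adjusted p = 0.241 with an estimated correlation), with Ndufs6 at -0.68 ± 0.16, Cox6a1 at -0.52 ± 0.13 and Atp5o at -0.53 ± 0.13 among the 15 that fell, and 1 rose. Atp5o overlaps 5 other genes. Erythroid genes had a median of -1.31 (camera, adjusted p = 1.14e-08; adjusted p = 0.188 with an estimated correlation). Car1, Tfrc (-1.14 ± 0.26) and Gata1 (-2.44 ± 0.77) fell within it. Its globin gene Hbb-bs was at 3.79 to 8587 CPM in Ova libraries and 13.2 to 4475 CPM in pIC libraries, so the list's median carries this spread too.

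Immediate early genes had a median of 0.50 (camera, adjusted p = 5.95e-07; adjusted p = 0.350 with an estimated correlation), and 5 of 21 rose, among them Egr1 (1.33 ± 0.30) and Ier2 (0.99 ± 0.19). Ribosomal protein genes had a median of 0.22 (camera, adjusted p = 3.96e-08; adjusted p = 0.350 with an estimated correlation), and 17 of 87 rose and 1 fell. The HSC identity list had a median of 0.27 (camera, adjusted p = 0.000145; adjusted p = 0.265 with an estimated correlation), and Pdzk1ip1 and Sult1a1 rose. In the megakaryocyte and platelet list (median -0.42, camera adjusted p = 0.000145), 6 genes fell and 1 rose, with adjusted p = 0.241 with an estimated correlation. These counts are adjusted over the list alone.

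The count of 11 depended on single pools. It was 0 without the PBS pool 5, the Ova pools 7, 8 or 9, or the pIC pool 14, 4 without the Ova pool 6 or the pIC pool 13, 6 without the PBS pool 4, 7 without the PBS pool 3, 16 without the pIC pool 12 and 17 without the Ova pool 10. Among single libraries it was 6 without Ova library 4 and 5 without pIC libraries 2 or 3. With libraries kept apart, limma-voom called 90 genes, 16 higher and 74 lower, with 9 of the 11 among them, and DESeq2 on the pools called 421.

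The fold changes of pIC and of Ova share their PBS pools. Their covariance across 17464 genes was 0.436 (correlation 0.458), where genes are not independent replicates. In 100 simulated sets with no effect it lay between 0.325 and 0.401, with a median of 0.367, because of the shared pools alone. The difference from that median was 0.0690. The correlation in the simulated sets was 0.491 to 0.551, above the observed one, so the 2 measures lay on opposite sides of their simulated ranges and no shared response is read from them. With the PBS pools divided between the comparisons, the covariance was 0.0361 to 0.230 and the correlation 0.0214 to 0.162 over the 6 divisions.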

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

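The tests on Y genes, on neutrophil genes, on Ppbp, on Cd48 and with thinned pools were chosen after the values they measure had been seen, at least in part. By the bound first written for Ppbp, its log2 fold change of 0.99 would have counted against platelets or megakaryocytes. That bound was widened by the SE after the value had been seen, which left the question open. The other tests were written down before their results.

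In 46 sets of values for groups of 4 to 10 samples, 3 had a sample far from the rest, and chance gives about 1 in 20. Iigp1 was at 482 CPM in the Ova pool 6, with the other Ova pools at 170 to 204 CPM. Top2a was at 205 CPM in the Ova pool 10, with the others at 47.5 to 85.5 CPM. Car1 was at 0.643 CPM in the Ova pool 7, with the others at 0 to 0.121 CPM.

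The Ova pools 6 and 10 bear on the list results for Ova against PBS. Depth was lower in Ova pools. With all PBS and Ova pools thinned to the shallowest of them the G2 and M median was -0.45 against -0.47 before. Thinning keeps each gene's expected share of its pool, so the median could move little under any cause. The refit shows only that the number of counts did not set the median. Other differences that go with depth stay open. Grouping by chance stays open for that list: 18 of the 56 splits of the 8 pools gave a camera p as small as the real one (8.74e-09), and the smallest of the others was 5e-37. The same holds for the interferon-gamma-inducible list, where 18 of 56 splits reached the real p of 0.000133 and the smallest other p was 2.29e-12. The treatment itself stays open as a cause of both.

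Other splits were run for every comparison. For genes called in Ova against pIC, 1 of 56 splits, the real one, gave as many as 11, and the highest of the others was 2. No smaller share can come from 56 splits. The splits take the pools as separate units, which the labels do not state. Chance is thus unlikely but not excluded. The same holds for interferon-stimulated genes in that comparison, with 1 of 56 splits at the real p of 1.46e-42 and the smallest other p at 1.25e-30. It does not hold for the cell cycle lists of Ova against pIC. For S phase the -log10 camera p was 24.0 in the real split and reached 38.4 in another. For G2 and M these values were 9.38 and 43.9. Grouping by chance thus stays open for both lists. For pIC against PBS, 3 pools against 3 make 10 splits, too few for a share under 0.05. The real split, 1 of 10, called 5 genes and the highest other 0. For the interferon-stimulated list the p was 1.74e-41 in the real split and 7.13e-19 in the nearest of the others, and for the S phase list 2.8e-15 and 4.35e-12. For Ova against PBS, with 0 genes called, all 56 of 56 splits gave as many, and the highest gave 1.

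Pf4 was above the highest PBS library in 5 of 5 pIC libraries, and Elane and Car1 in 3 of 5 each, not all the same ones. For mature neutrophils in the sort, the median log2 fold change of S100a8, S100a9, Ngp and Camp in pIC against PBS was -0.95. S100a8 was at 9.14 ± 2.10 against 19.1 ± 7.38 CPM. None of these genes passed (edgeR, adjusted p = 0.457 to 0.988), and Ngp and Camp were near the floor, at 0.336 and 0.870 CPM in pIC pools. The values show no rise and so argue only weakly against mature neutrophils. The sort removed cells with lineage markers. Platelets or megakaryocytes cannot be told apart from a change within stem cells by Ppbp, an abundant platelet transcript, at 0.99 ± 0.99 (13.3 ± 15.2 CPM, beside 960 ± 373 CPM of Pf4), or by the list, where Itga2b (1.33 ± 0.31) and Gp1bb (1.92 ± 0.54) rose and Gp9 (-0.91 ± 0.32), Selp (-1.08 ± 0.38), Itgb3 and Thbs1 (-2.02 ± 0.36) fell, adjusted over the list alone. More progenitors may have entered the Sca-1 gate, since Ly6a differed by 1.22 ± 0.22, but Cd48, which most progenitors carry, differed by 1.41 ± 0.71 without passing (adjusted p = 0.468), so this stays open. A response of the stem cells to poly I:C also stays open.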

How the results depend on the processing

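The settings that thin pools, that fit presence of Mmrn1, or that leave out the pIC library 4 or the pIC pool 12 with each library as 1 replicate, were chosen after seeing the data; all others were planned beforehand. No called value changed sign under any setting. Counts of called genes are given in the order pIC against PBS, Ova against PBS and Ova against pIC, with 5, 0 and 11 in the pools. They were 350, 6 and 131 with each library as 1 replicate, 286, 12 and 90 by limma-voom with a correlation for title numbers, 519, 41 and 421 by DESeq2 and 47, 1 and 28 by limma-trend on the authors' normalized values. With each library as 1 replicate they were 252, 7 and 34 without the pIC library 4, and 179, 4 and 83 without the pIC pool 12. The first was 11 with presence of Mmrn1 as a covariate, 12 with no composition factor, 1 with no filter, 57 with at least 10 CPM in at least 3 pools and 0 with only the 2 groups compared, and the third was 26 and 7 under the last 2 of these. The cause of these differences was not tested. The number of replicates was larger where libraries were kept apart, but DESeq2 gave its counts on the same pools as edgeR.

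Replicate numbers of the labels did not pair libraries across treatments: the mean correlation of same-numbered libraries was 0.0187, 0.0193 and 0.0290 for the 3 pairs of groups, with single pairs between -0.0361 and 0.0846, against 0.1 needed for each pair. With the replicate block the counts were 240, 32 and 303.

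Leaving out 1 pool or library gave 0 to 29 genes in pIC against PBS, 0 in every refit of Ova against PBS, and 0 to 17 in Ova against pIC. The median of interferon-stimulated genes was 0.92 to 1.11, 0.10 to 0.27 and -0.83 to -0.66 in the 3 comparisons. That of S phase genes in pIC against PBS was 0.63 to 1.15. In Ova against PBS that of G2 and M genes was -1.01 to -0.23, and that of interferon-gamma-inducible genes was 0.18 to 0.54.

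The interferon-stimulated list in Ova against PBS (0.19) passed camera with each library as 1 replicate (0.17), with the replicate block (0.22), with no composition factor (0.26), with the strict filter (0.24), by limma-trend (0.20), with thinned pools (0.22), and without the pIC library 4 or pool 12 (0.17 and 0.16). With an estimated correlation and by fry's directional test, the G2 and M list (-0.47) and the interferon-gamma-inducible list (0.45) in Ova against PBS, and the S phase list (0.89) in pIC against PBS, were not called. Over all settings, 3818 list results stayed on their side of the threshold, 157 lost their call and 72 gained it; for named genes these numbers were 3431, 227 and 189.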

Other observations

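The test on Y genes and the fit with Mmrn1 were chosen after their values had been seen; the tests on X-linked genes were set before.

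The pIC pool 12 had 2.69 CPM of Xist, while the other 10 pools had 1335 to 2848 CPM. A male animal is argued against by the Y genes: Ddx3y and Eif2s3y together were at 0.326 CPM in pool 12 and 0.0406 to 1.06 CPM in the others, and Kdm5d, with counts in every pool, was at 2.20 CPM against 2.24 to 5.95 CPM. Had Xist been lost with 2 active X chromosomes, X-linked genes would have risen, but the median log2 ratio of 331 of them to the other pools, relative to 9455 autosomal genes, was -0.0108. Kdm6a, Ddx3x, Eif2s3x and Kdm5c, transcribed from both X chromosomes in female mice, had a median log2 ratio of -0.61 in pool 12 and -0.17 to 0.27 in the other pools. This is consistent with a single X chromosome in the cells of that pool, as a hypothesis, and loss in the animal or only in its marrow cannot be separated here.

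Both libraries of pool 12 lacked Xist and no other library did, with an escape gene ratio of -0.61 over both. Mmrn1 was also shared by title number: it was at 0 to 0.270 CPM in all 9 libraries of 4 pools and at 83.1 to 327 CPM in all 17 of the others, and the only gene so split. The split is consistent with a difference between animals, with 1 animal or 1 genotype behind each number, as a hypothesis that the labels do not give. It is uneven between the groups (1 of 3 PBS, 1 of 5 Ova and 2 of 3 pIC pools), but with presence of Mmrn1 in the fit the interferon-stimulated median in pIC against PBS was 1.11 and not 1.06, and 11 genes were called and not 5. Without pool 12, interferon-stimulated genes that rose in pIC against PBS, adjusted over the list alone, numbered 36 and not 33.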
